A study of Homo sapiens with 6 samples.

How the data were processed

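The series describes RNA sequencing of MCF-7 cells, an established human breast cancer cell line that expresses the estrogen receptor. Per the labels, 6 libraries were made, 3 from control cells and 3 from cells exposed to PM2.5, the fine fraction of airborne particulate matter. Per the labels' protocols, total RNA was extracted with TRIzol 48 h after exposure, and libraries were prepared with an NEBNext Ultra RNA kit and sequenced on an Illumina NovaSeq instrument. The genome build GRCh38 is named in the submitters' processing notes. The aligner and the counting tool are not given in the sources used here.

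The only gene-level table available here was examined. Its header was compared with the title and description of every sample, by name alone. Of its 9 columns of per-sample values, 0 carried the name of a sample of the series, and all 9 were left out. The column names begin with Nthy, a word that no label of these samples contains, and form 3 sets of 3 columns. One of these sets is marked CK, and the other 2 are marked 2021 CQ and 2023 CQ. In the sample titles, CK marks the control libraries and CQ the PM2.5 libraries. The labels describe a single CQ group and give neither 2021 nor 2023. The names thus tie no column to an MCF-7 library. The counts of a few genes, chosen after the values were seen, were also read over all 9 columns together to describe what the table holds. Genes that MCF-7 cells are known to express strongly were at or near 0: the deposited counts ranged from 0 to 9 for ESR1, the estrogen receptor, from 0 to 2 for TFF1, one of its targets, from 0 to 12 for CDH1, the epithelial cadherin, and from 4 to 24 for EPCAM, an epithelial surface protein. PAX8 and FOXE1, transcription factors of the thyroid, had counts of 5194 to 10893 and 1384 to 2939. FN1 (fibronectin) had 60690 to 262516 counts and COL1A1 (a collagen chain) 6481 to 88538. Not every gene expressed in MCF-7 cells was low, since the keratin gene KRT8 had 15511 to 24186 counts and GREB1, another estrogen receptor target, 142 to 1054. The near absence of ESR1, TFF1, CDH1 and EPCAM in all 9 columns goes against their being MCF-7 libraries under other names. The sources used here do not say which cells or which study the columns come from. No column was therefore given to a sample or a group.

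The comparison planned before the data were examined was a quasi-likelihood test of PM2.5 against control libraries, with treatment as its only term. Tests of gene lists fixed in advance were planned with it. Several alternative settings were planned as well, among them a replicate block, which the main fit did not have. None of these was run, since no column was matched to a library, and no depth, fold change or p-value is reported.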

Results

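The study addressed how exposure to PM2.5 alters the transcriptome of MCF-7 breast cancer cells. The labels describe 6 RNA sequencing libraries, of which 3 came from control cells and 3 from PM2.5-exposed cells, with RNA extracted at 48 h. The contrast implied by this design is PM2.5 against control.

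Expression in the MCF-7 libraries could not be analysed from the only gene table available here. The gene table examined held 9 columns of per-sample values, and 0 of them carried the name of any of the 6 libraries. Its columns were named Nthy and fell into 3 sets of 3. Of these, 2 sets, marked 2021 and 2023, carried CQ. The labels describe a single CQ group, the PM2.5 libraries. The estrogen receptor gene ESR1, which MCF-7 cells express, had at most 9 counts in any of the 9 columns. No gene, gene group or library depth is reported for either group, and no difference between PM2.5 and control cells was tested.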

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

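The number of columns matched to a library was counted again under other rules for a match, chosen after seeing the data. The main rule accepted a column name that held, or lay within, a title or description, and its count was 0. Requiring the name to equal a title or description is stricter, so its count of 0 followed from the main rule. With the cell line ignored and the ending alone compared (CK or CQ and the number), all 9 columns shared an ending with a library. This match does not make them MCF-7 libraries, since ESR1 had at most 9 counts and EPCAM at most 24 in any of them. Of the 9 columns, 6 shared their ending with another column, so 3 libraries would each have had a pair of columns competing for them, one from the set marked 2021 and one from the set marked 2023. No label of the series gives either number. The ending says nothing of the cells, so this rule was not used to assign any column. No paired analysis was possible because no column was matched to a library. With no column matched, none of the expression tests and alternative settings planned before the data were examined was run.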
